A study of Homo sapiens with 2 samples.

How the data were processed

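SF3A1, a subunit of the SF3A complex of the U2 small nuclear ribonucleoprotein (snRNP), was immunoprecipitated from ultraviolet-crosslinked C4-2B cells in 2 libraries. C4-2B is a prostate cancer line of the LNCaP lineage; the cells were of a derivative prepared for CRISPR interference. Per the labels' protocols, cells were harvested 48 h after seeding, crosslinked at 254 nm with 400 mJ/cm2, and 2 µg of antibody was used. The labels name 1 group and no control group, so no comparison between groups of samples was made. Input or mock libraries were not analysed here.

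The data consist of 1 list of single-base positions, which its name describes as pooled over the libraries, restricted to unique tags, limited to deletions and filtered at an FDR of 10 percent by crosslink-induced mutation site (CIMS) analysis. Reverse transcriptase can skip a crosslinked base, so a deletion in a sequenced tag can mark the contact between protein and RNA. For each position the authors deposited a count of tags with the deletion, and the position's name also holds the count of tags over it and an index. Both counts are whole numbers and were used as deposited, without normalization, and the 2 copies of the deleted-tag count were equal on all 2960 lines. The submitters' processing notes name cutadapt, BWA 0.7.17, SAMtools and UMI-tools, and build hg38. Their roles, settings and the version of the CIMS software are not given in the sources used here. The other deposited text field, the position's name, carries no score of its own. Because the list is pooled, no value could be split by library, no spread between replicates could be computed, and depth per library is unknown. Tags over the sites summed to 246057, of which 213787 carried the deletion. Intervals for a deleted share are exact Clopper-Pearson 95% intervals; they cover counting error only and assume that tags are independent molecules, a point taken up in the closing section.

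Sites were assigned to genes with the RefSeq gene table of GRCh38.p14, which shares its primary chromosome coordinates with hg38. The table gives gene bodies without strand, exons or sequence. Of its 59792 rows, 58993 on the primary chromosomes were used; rows of other scaffolds that carry a chromosome's number, repeated symbols and unplaced genes were left out. Each site received 1 class in the order rRNA, snRNA, snoRNA, other small RNA, protein-coding, long noncoding, pseudogene or other, and no annotated gene. Mitochondrial sites and sites on unplaced contigs formed classes of their own. A gene counted as having a site if a site on either strand fell in its body. Positions within a gene were counted from the 5′ end as read along the site's own strand. Coordinates are 1-based.

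Gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The 22 lists were tested by the number of members with at least 1 site, using an exact two-sided test against random lists of the same size matched on 10 strata of gene-body length (convolved hypergeometric distributions). The background was the 19866 nuclear protein-coding genes, or all nuclear genes for the lists of snoRNA hosts and long noncoding RNAs, with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. 5 genes stood in 2 lists each. Distances between neighbouring sites of a gene and strand were compared with 10000 uniform placements over the gene body. The named genes were the 12 with the most sites, the 10 sites with the most deleted tags, up to 4 members per list with the most sites, every snRNA family with a site, and SF3A1 and CCDC157. Some genes that this rule picks, and 1 of the lists, are not described. Other genes named here were chosen after their values were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

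The list test was tested on simulated data in which 2558 sites were placed by gene length over the protein-coding genes. It made 0 calls among 400 list tests without an effect. With the site rate of list members raised 5-fold, it called the ribosomal protein list in 6 of 20 runs, the hnRNP list in 7 and the chaperone list in 9. The distance test gave a p of 0.204 for uniform sites and 0.000999, the smallest value its simulated draws could give, for planted groups.

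Planned comparisons with exon and intron classes, splice sites, the deleted base and surrounding 5-mers need an exon annotation or genome sequence and were not run here. The annotation-class and distance comparisons were therefore made on whole gene bodies. Alternatives covered sites with more deleted tags than the median, merging within 50 nt, 1 site per gene, sites with a deleted share under 0.4, and removal of small RNA, mitochondrial and overlapping genes. Sites with a deleted share under 0.9 and a narrower background for the lists of snoRNA hosts and long noncoding RNAs were added as alternatives after the data had been seen, as were the comparisons of strand, of position along the gene and of the deleted share itself.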

Results

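The deposited list held 2960 deletion sites from anti-SF3A1 crosslinking and immunoprecipitation of C4-2B prostate cancer cells, pooled over 2 libraries. Such a list is meant to show where on RNA the splicing factor SF3A1 makes contact. Sites were covered by a median of 54 tags (interquartile range 29 to 95.25, maximum 2630), of which a median of 50 carried the deletion (interquartile range 28 to 90). No site had fewer than 13 deleted tags. The 2 strands held 1510 plus and 1450 minus sites. The index numbers in the position names rose with position on each of the 52 chromosome and strand combinations; their meaning is not given in the sources used here. If they number deletion positions from 0, the numbers add up to at least 8764 positions, of which 33.8% or less were in the list. Because the libraries were pooled, no value below carries an error between replicates, and p-values refer to genes or sites of this pool.

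Most sites lay in the bodies of protein-coding genes. These held 2558 of the 2960 sites, or 86.4% (95% Clopper-Pearson interval 85.1 to 87.6). Another 156 sites (5.27%, 4.49 to 6.14) lay in long noncoding RNA genes and 169 (5.71%, 4.90 to 6.61) outside any annotated gene. Small structural RNAs took few sites but held them at high density. The 14 snoRNA sites came to 106 per Mb of annotated snoRNA and the 6 snRNA sites to 319 per Mb. Protein-coding gene bodies, introns included, held 2.03 sites per Mb, long noncoding genes 0.428 per Mb and unannotated sequence between the first and last gene of each chromosome 0.131 per Mb. The mitochondrial genome held 30 sites, 22 on the plus and 8 on the minus strand, and unplaced contigs held 7. Among the 222 sites with a deleted share under 90%, protein-coding gene bodies held 65.3%. The densities are not corrected for RNA abundance.

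Within a gene, sites lay almost always on the same strand. Of 610 pairs of neighbouring sites in nuclear genes that overlap no other annotated gene, 599 shared a strand (98.2%, 95% Clopper-Pearson interval 96.8 to 99.1). All sites lay on 1 strand in 371 of 381 such genes with several sites (exact binomial test against an even chance, two-sided, p = 6.58e-96). Sites were spread along the whole gene body: of 2336 sites in protein-coding genes without an overlapping gene, 254 lay in the first of 10 equal parts of the gene and 259 in the last, and the parts between held 208 to 247 each, against 233.6 expected by even spread (chi-square test, p = 0.290). Neighbouring sites of a gene were a median of 16179 nt apart, closer than the median of 18781 nt (95% of placements 16701 to 20957) from uniform placement over gene bodies (one-sided Monte Carlo p = 0.0067, n = 661 pairs in 402 gene and strand combinations). Only 3 of these pairs (0.454%) lay within 10 nt of each other, against 0.163% by uniform placement, an excess that did not pass the threshold (one-sided Monte Carlo p = 0.0886, n = 661 pairs).

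The 2558 protein-coding sites fell in 1953 genes when each site was given to 1 gene. Placement by gene length alone gave 2005 genes (95% of draws 1967 to 2043, one-sided Monte Carlo p = 0.0034, n = 2558 sites). The draws lacked the rule that gives a site in overlapping genes to the shorter of them. Counting overlapping genes too, 2014 protein-coding genes, or 10.1% of the background, held a site. This count lay inside the range of the draws, so a concentration beyond gene length is not established. Of the 2014 genes, 1598 held 1 site, 291 held 2 and 125 held 3 or more. Genes with a site had a median length of 61.7 kb, against 24.5 kb for all protein-coding genes.

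The genes with the most sites included long noncoding RNAs, protein-coding genes and mitochondrial genes. MIR99AHG, the host transcript of a microRNA cluster on chromosome 21 (16070488 to 16631727), held 25 sites, all on the plus strand and between 16271894 and 16572602. MALAT1, an abundant nuclear RNA on chromosome 11 (65497738 to 65506516), held 17 sites, or 194 per 100 kb, all on the plus strand; 16 of them also fell in the annotated body of its antisense transcript TALAM1. ANK3, which encodes a membrane-cytoskeleton adaptor, held 16 sites, and NEAT1, the paraspeckle RNA, 15. PPP3CA, the catalytic subunit of calcineurin, held 10 and the noncoding MYC neighbour PVT1 held 9. The mitochondrial 16S rRNA gene RNR2 held 8 sites, which include a base counted once on each strand. ND4, a complex I subunit, held 6. The adhesion molecule gene NCAM2, the ephrin gene EFNA5 and NAALADL2 held 7 each. Neither SF3A1 (chromosome 22, 30331988 to 30356894) nor its neighbour CCDC157 (30356624 to 30378673) held a site; the list contains only positions past the authors' FDR, so this says nothing of their coverage.

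RNA-processing genes carried sites more often than length-matched genes. All tests of gene lists below are two-sided, with p-values adjusted by the Benjamini-Hochberg method over the 22 lists. Among SR proteins, which bind exons and promote splicing, 10 of 16 genes had a site against 1.12 expected (exact test, adjusted p = 1.27e-07). SRRM2 held 5 sites and SRSF2, SRSF11 and SRSF3 held 2 each. Among hnRNP proteins, 10 of 24 had a site against 1.81 expected (exact test, adjusted p = 2.64e-05), with 5 sites in HNRNPU, 3 in HNRNPL and 2 each in HNRNPC and HNRNPH1. Of U1 snRNP and 5′ splice site factors, 7 of 19 had a site against 1.65 expected (exact test, adjusted p = 0.00342), including LUC7L3, LUC7L and TIA1 with 1 site each. Of the U2 snRNP proteins, 6 of 24 had a site against 2.02 expected (exact test, adjusted p = 0.0468): SF3B3 and the helicase DHX15 with 2, and PHF5A, SNRPA1, U2SURP and SF3B1 with 1. The U2 call was lost without length matching (6 genes against 2.43 expected, exact test, adjusted p = 0.0991) and among sites with more deleted tags than the median (2 genes against 1.05 expected, adjusted p = 0.885).

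Genes of protein synthesis and folding were also above expectation. Of 77 cytosolic ribosomal protein genes, 23 had a site against 2.81 expected (exact test, adjusted p = 2.43e-14); RPL6 held 4, RPL3 and RPS18 held 2, and the single site in RPS2 had 234 deleted tags. Ribosomal protein genes have many processed pseudogenes that can share reads, so these assignments are uncertain. Of 31 translation factors, 13 had a site against 2.52 expected (exact test, adjusted p = 2.2e-06), with 3 sites each in EIF4A2 and EIF4B and 2 each in EIF3B and EIF3E. Of 33 chaperone and secretory pathway genes, 10 had a site against 2.30 expected (exact test, adjusted p = 0.000302), among them HSPH1 with 3, HSP90AA1 with 2, and SEC61A1 and HSPA8 with 1. Host genes of snoRNAs were tested against all nuclear genes, so their ratio cannot be ranked against those of the protein-coding lists. Of these hosts, 12 of 21 had a site against 0.635 expected (exact test, adjusted p = 8.91e-14). EIF4A2, TAF1D and SNHG1 held 3 sites and NOP58 held 2. Some of these sites lie in the snoRNA itself, such as SNORD2 in EIF4A2, SNORD30 in SNHG1 and SNORD11 in NOP58; without small RNA, mitochondrial and overlapping genes 9 hosts had a site against 0.5 expected (exact test, adjusted p = 1.09e-09). Among 12 nuclear long noncoding RNAs, 5 had a site against 0.909 expected (exact test, adjusted p = 0.00404): MALAT1, NEAT1, PVT1, OIP5-AS1 and KCNQ1OT1. This last call was lost without small RNA, mitochondrial and overlapping genes, which were left out together (3 genes against 0.766 expected, exact test, adjusted p = 0.122).

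Genes of the prostate lineage carried sites above expectation and genes of other tissues did not. Of 21 protein-coding luminal and lineage genes, 7 had a site against 1.81 expected (exact test, adjusted p = 0.00416), including 2 sites in GRHL2 and 1 each in CDH1 and AMACR. The recurrently altered prostate cancer genes had 10 of 36 against 5.57 expected (exact test, adjusted p = 0.134), including KMT2C with 3 sites, and ATM and KMT2D with 2 each. No site fell in 20 basal and neuroendocrine genes (1.65 expected, exact test, adjusted p = 0.484). The 4 lists of hepatocyte, neural, blood and stromal genes each had 1 of 20 members with a site, MBP among the neural, CD4 among the blood and TTN among the stromal genes, against 1.36, 2.74, 1.07 and 2.33 expected (exact tests, adjusted p of 1, 0.586, 1 and 0.774). Gene strand was not known, so these sites need not lie on the RNA of the named gene. The 2 TTN sites also lay in the body of TTN-AS1. Without small RNA, mitochondrial and overlapping genes, no stromal gene had a site. The lineage call was lost among sites with more deleted tags than the median (3 genes against 0.999 expected, exact test, adjusted p = 0.316).

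Among the metabolic and proliferation lists, glycolysis passed the threshold narrowly. Glycolysis genes had 5 of 17 with a site against 1.53 expected (exact test, adjusted p = 0.0481): PFKL with 2, and GPI, LDHB and ENO1 with 1 each among them. This call was lost without length matching (5 genes against 1.72 expected, exact test, adjusted p = 0.0855) and among sites with more deleted tags than the median (3 genes against 0.807 expected, adjusted p = 0.209). Oxidative phosphorylation genes had 4 of 35 against 2.01 expected (exact test, adjusted p = 0.428), with 2 sites in ATP5F1B, 1 of them in SNORD59B, and 1 in NDUFV1, ATP5MC1 and NDUFS3. Cell cycle genes had 3 of 31 against 2.73, namely TOP2A, KIF11 and MCM3, and genes of epithelial-mesenchymal transition had VIM and ITGB1, 2 of 22 against 2.28 (exact tests, adjusted p of 1 for both). The 29 replication-dependent histone genes, which lack introns, had no site, against 0.430 expected (exact test, adjusted p = 1). In all, 12 of the 22 lists were above and 0 were below expectation; 1 of the 12 is not described here. Only 5 of the 12 calls held among the 222 sites with a deleted share under 90%: hnRNP proteins, translation factors, chaperones, snoRNA hosts and nuclear long noncoding RNAs. RNA abundance was not measured in these data, so the counts cannot separate abundance from contact. Whether sites with the deletion in every tag mark contact at all is not settled, as the closing section describes.

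**Figure D1:**
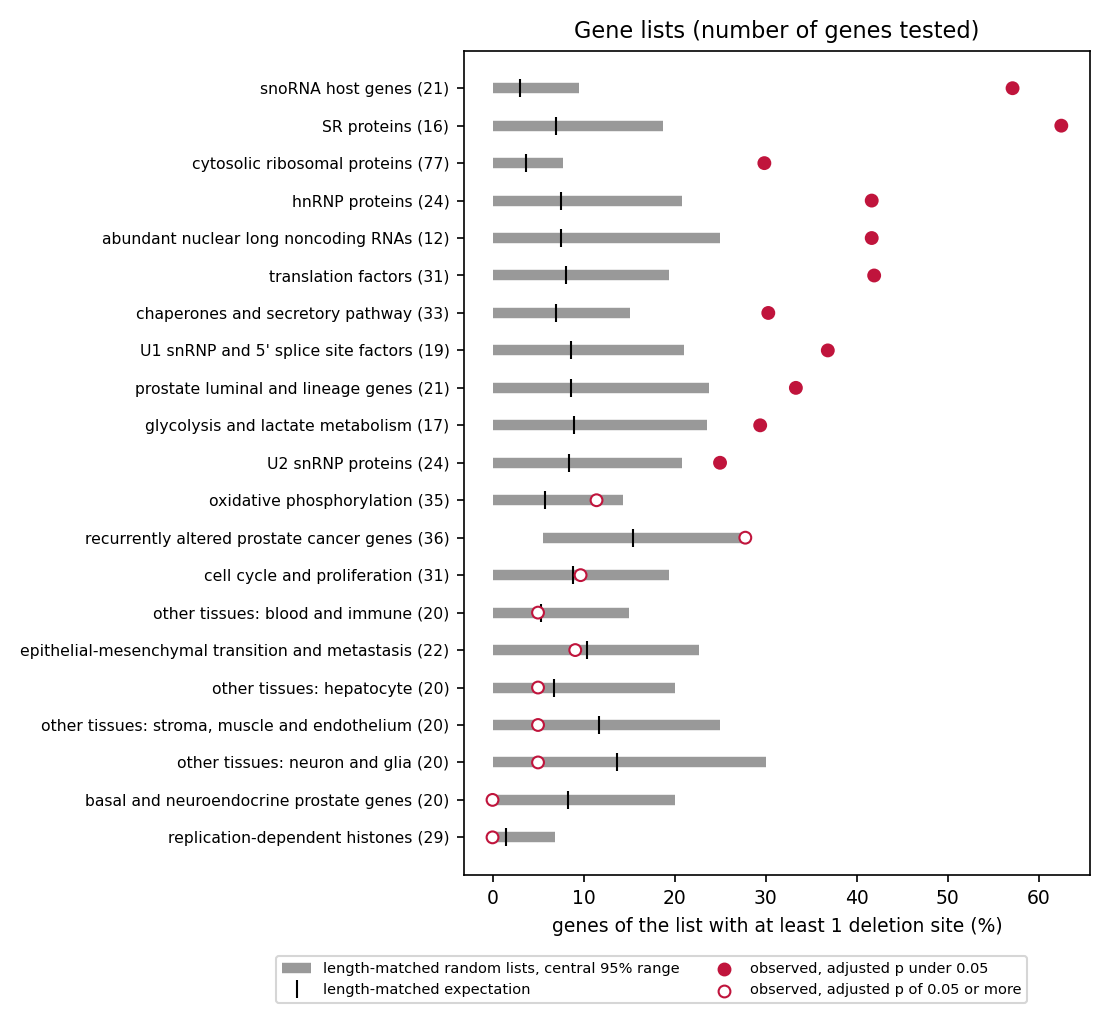
Percentage of the genes in each list described here that held at least 1 deletion site in the pooled list (points), with the length-matched expectation (black ticks) and the central 95% range of length-matched random lists (grey bars); the number of genes tested is in parentheses. SR protein genes reached 10 of 16 and snoRNA host genes 12 of 21, while the 4 lists of other tissues held 1 of 20 each.

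Spliceosomal snRNAs held 6 sites in 3 families. U2 snRNA, the RNA partner of SF3A1, held 3 sites in the RNU2-2 gene on chromosome 11, which lies inside the WDR74 gene body, at positions 86, 92 and 130 of 191. Their deleted shares were 6.39% of 798 tags (95% Clopper-Pearson interval 4.80 to 8.32), 4.07% of 811 (2.82 to 5.67) and 11% of 118 (6.0 to 18.1). U1 snRNA, which pairs with the 5′ splice site, held 2 sites in variant gene copies on chromosome 1: position 149 of 164 in RNVU1-7 with 18.3% of 813 tags (15.7 to 21.2), and position 154 of 167 in RNVU1-19 with 95.9% of 73 tags (88.5 to 99.1). The U5 variant RNU5D-1 held 1 site at position 80 of 102, with 84.2% of 19 tags (60.4 to 96.6). U1 and U2 genes have near-identical copies that share reads, so the family rather than the copy is identified. Among the 14 snoRNA sites, deleted shares ranged from 11.4% of 229 tags in SNORD83B to 100% of 214 tags in SNORD11. SNORD2 had 31.6% of 430 tags and SNORD30 21.7% of 276.

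At most sites the deletion was present in every tag. This was so at 2243 of 2960 sites (75.8%, 95% Clopper-Pearson interval 74.2 to 77.3), 2738 sites had a share of 90% or more, and the median share was 100%. Among the 37 sites with over 400 tags, 22 had a share under 40%, against 22 of the 2271 sites with fewer than 100 tags. Each listed site has at least 13 deleted tags, so the listing itself limits low shares at low coverage. The 10 sites with the most deleted tags all had shares above 99%. They lay in the bodies of GPRC5A (2628 of 2630 tags), NETO1 (1614 of 1615), DIO3OS (1545 of 1545), UBASH3B (1418 of 1418), PLCXD1 (1415 of 1421), STRBP (1390 of 1400), LIMK2 (1303 of 1303), DHPS (1258 of 1268), SMC4 (1215 of 1215) and LOC105376626 (989 of 990).

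**Figure D2:**
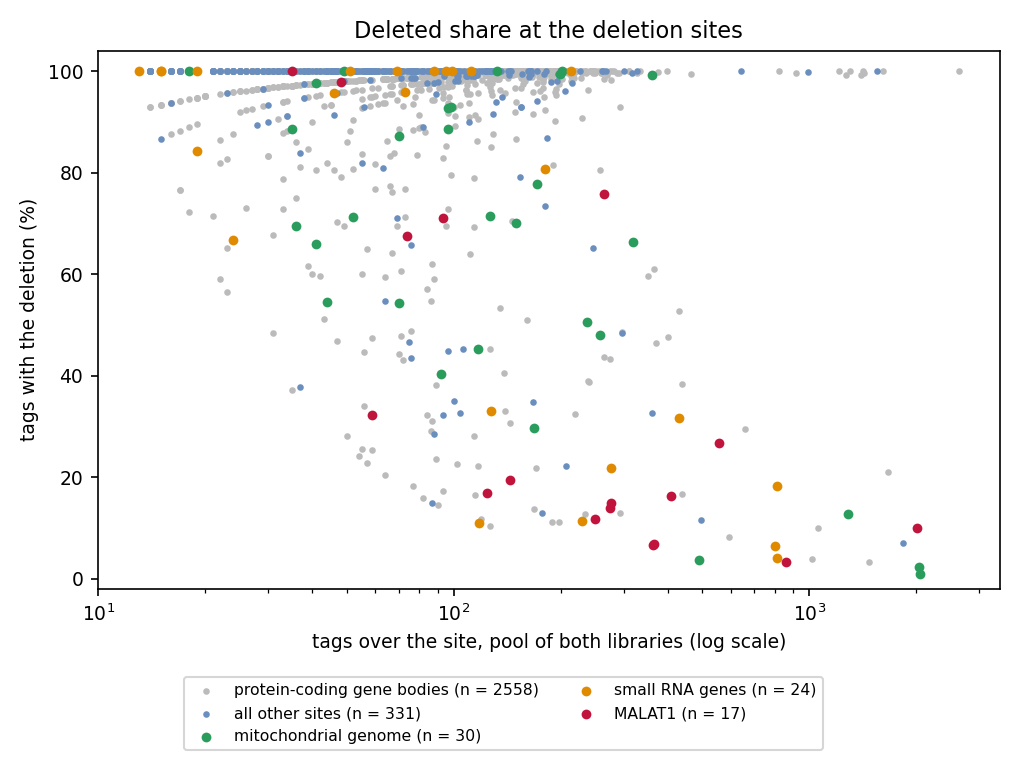
Percentage of tags with the deletion at each of the 2960 sites against the number of tags over the site in the pool of both libraries, on a log scale; colours mark the kind of gene. Most points lie at 100%; 15 of the 17 MALAT1 sites and 21 of the 30 mitochondrial sites lie under 90%.

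Deleted shares were low at many mitochondrial and snRNA sites, which also had higher coverage. The median share was 70.6% over 30 mitochondrial sites, 14.7% over 6 snRNA sites and 97.8% over 14 snoRNA sites, 7 of which were complete. All 4 sites in other small RNAs were complete and were not in the test that follows. Shares averaged 64.8% ± 34.8 (SD over 50 sites) in snRNA, snoRNA and mitochondrial genes and 97.1% ± 11.7 (SD over 2558 sites) in protein-coding genes (permutation test, two-sided, p = 2e-05, the smallest that 100000 permutations can give), at median coverages of 117.5 and 52 tags. MALAT1 and NEAT1, neighbouring nuclear RNAs on chromosome 11, differed: the mean share was 34.8% ± 33.4 (SD over 17 sites) in MALAT1 and 89.6% ± 16 (SD over 15 sites) in NEAT1 (permutation test, two-sided, p = 2e-05; adjusted over both comparisons p = 2e-05). A share under 90% was found at 15 MALAT1 sites and 5 NEAT1 sites, at median coverages of 264 and 55 tags. Both share comparisons were chosen after the data had been seen. With at least 13 deleted tags per listed site, the lowest share that can be listed rises as coverage falls. Low shares could still be listed at lower coverage: 22 of the 2271 sites with fewer than 100 tags had a share under 40%. Coverage differed between the groups compared, so the p-values do not separate the kind of gene from its coverage. The best covered MALAT1 site, at 65503947, had 10.0% of 2011 tags (95% Clopper-Pearson interval 8.77 to 11.4). Of the NEAT1 sites, 9 lay within the first 4000 nt of its 22743 nt body, where 2.64 were expected by even spread; this window was chosen after the positions were seen, so no test is given. Among protein-coding genes, 3 of the 4 sites in KLK3, which encodes prostate-specific antigen, had partial shares, of 54.7%, 24.1% and 31.0%. The HSP90AA1 sites had 10.0% of 1060 tags and 14.4% of 90, and the HSP90AB1 site had 22.2% of 117.

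**Figure D3:**
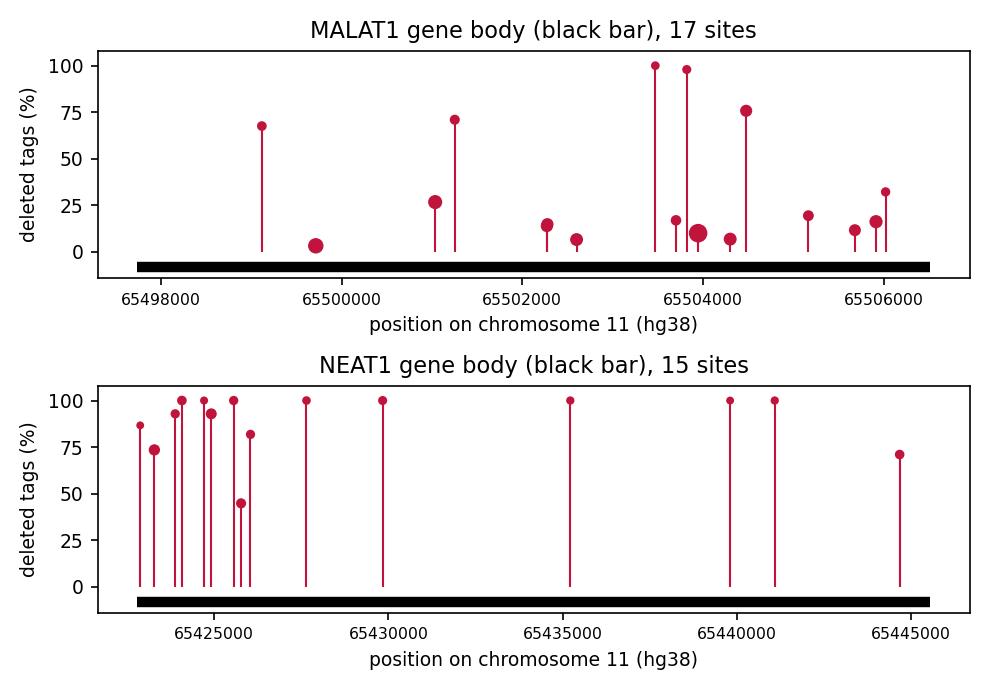
Deletion sites along the MALAT1 and NEAT1 gene bodies (black bars) by hg38 position on chromosome 11; stem height is the percentage of tags with the deletion and point area grows with the number of tags over the site. MALAT1 shares lie mostly under 35% and NEAT1 shares mostly above 70%.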

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

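The setting of a deleted share under 0.9 was chosen after the data had been seen. The share of sites in protein-coding gene bodies, 86.4% as reported, was within its interval when sites were merged within 50 nt, widened by 10 nt, limited to 1 per gene or limited to those with more deleted tags than the median. It was 88.1% without small RNA, mitochondrial and overlapping genes, a setting that by construction removes other classes. Sites with a share under 0.9 numbered 222, with 65.3% in protein-coding bodies and 5 lists above expectation; sites with a share under 0.4 numbered 79, with 53.2% and 3 lists. Sites with more deleted tags than the median numbered 1466 and gave 8 lists, against 12 as reported; the other settings gave 11 or 12. With so few sites left under 0.4 and 0.9, lost calls do not show that those lists lack sites. Without length matching the recurrently altered prostate cancer genes were above expectation (exact test, adjusted p = 0.0106). Under a share of 0.4 the median distance between neighbouring sites was 355 nt against 438 nt by placement, which did not pass the threshold (one-sided Monte Carlo p = 0.272, n = 15 pairs). Under a share of 0.9 it was 339 nt against 741 nt, which did (one-sided Monte Carlo p = 0.0022, n = 26 pairs). Of the sites under 0.9, 15 lay in MALAT1, 14 of them also in TALAM1, and 5 in NEAT1. A few genes thus weigh heavily in these pairs. The share of neighbours within 10 nt among all sites, 0.454% against 0.163%, did not pass the threshold (one-sided Monte Carlo p = 0.0886, n = 661 pairs). snRNA sites numbered 3 among those with more deleted tags than the median and 4 after merging within 50 nt, against 6 as reported. Strand agreement was 100% under a share of 0.4, but over 2 pairs, too few to test. None of the 12 list calls reversed under any alternative that was run. Expected counts were so low that even a list without a site could hardly be called below expectation, so this is no support for the calls. Leaving out a replicate was not possible in a pooled list. The comparisons that need exons or sequence, matching on exon length, counting exonic sites alone, removing homopolymer sites and using 1 transcript per gene were not run. Depth limits low shares: with at least 13 deleted tags per site, a position with 100 tags and a share under 13% is not in the list. No paired analysis was possible because the labels give 1 group.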

Other observations

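Every test in this part was chosen after the data had been seen, except the intraclass correlation over complete sites, whose prediction was fixed before its result. Protein-coding genes were also grouped by the letters that open their symbols, and the 148 groups with at least 15 members were tested against length-matched genes with the same exact two-sided test and Benjamini-Hochberg adjustment. By this exact test, symbols opening with RPL (16 of 52 with a site, 2.04 expected, adjusted p = 1.12e-08), RPS (12 of 45, 3.05 expected, adjusted p = 0.00132) and EIF (14 of 56, 5.08 expected, adjusted p = 0.0198) were above expectation. These 3 groups share many genes with the lists of ribosomal proteins and translation factors, so they are no separate evidence. The RPS group also holds genes outside those lists, such as RPS6KA1. Olfactory receptor genes, opening with OR, held no site in 389 genes against 13.1 expected (exact test, adjusted p = 0.000155), and uncharacterised LOC genes held sites in 9 of 511 against 23.5 (adjusted p = 0.0198). Cytochrome P450 genes (CYP) had 0 of 56 against 4.97 expected, collagen genes 2 of 44 against 7.83 and RNA-binding motif genes (RBM) 10 of 39 against 4.21, but none of these 3 passed the adjustment (adjusted p of 0.249, 0.279 and 0.263).

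Chromosome 21 held 52 plus and 9 minus sites. MIR99AHG accounted for 25 of the plus sites and NCAM2 for 7, and since sites of a gene share a strand, no test over sites is given. The densest 1 Mb stretch of the list, 34 plus-strand sites between 65415204 and 65634519 of chromosome 11, held NEAT1 and MALAT1.

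At most sites the deletion was in every tag. Tags from genomic DNA would put neighbouring complete sites of a gene on the same strand in about 50% of pairs, and the 98.2% found (378 of 385) argues against them. Tags that are copies of 1 molecule predict that the tag number does not follow the gene. Over 647 complete sites in 262 genes the intraclass correlation of log2 tags was -0.0201 (bootstrap 95% interval -0.104 to 0.0652), which is consistent with such copies. Over 50 sites with shares under 0.9 in 13 genes, a cut chosen after the data had been seen, it was 0.232 (permutation p = 0.044). No interval was computed for this second value. It may rest on few genes, since MALAT1 held 15 of the sites under 0.9, so the 2 values are not ranked. The list's name says unique tags and the submitters' processing notes name UMI-tools, so such copies should have been removed, and this could not be examined here. Crosslinking in a part of many independent molecules forbids complete deletion. The median share of 1 restates the pattern and is no separate test of this. Well-covered complete sites, such as DIO3OS with 1545 of 1545 tags (95% Clopper-Pearson interval 99.8 to 100), argue against it for those sites. Small deletions in the genome of C4-2B, read from independent molecules of both alleles, stay open, since a deletion on all copies of a chromosome gives complete sites; the 2.80% of sites with a share of 0.3 to 0.7 does not decide this. With 1 group in the labels, no biological explanation was tested.

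The 2 U1 snRNA sites lay at positions 149 and 154, in the part of U1 that forms its last stem-loop, a known contact of the SF3A1 ubiquitin-like domain. Uniform placement gives this with probability 0.0296 if the sites are independent, and 0.18 if reads shared between copies make them 1 site, so chance placement cannot be told apart from contact at that stem-loop. The U2 sites lay at 86, 92 and 130 of 191, so none was as close to the 3′ end as the U1 sites. Their positions were not tested. Merging within 50 nt left 4 of the 6 snRNA sites, so close U2 sites need not be separate contacts.

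A position of the mitochondrial genome in RNR2 had a deletion site on both strands, with 202 of 202 tags on the minus and 27 of 41 on the plus strand. The number of positions of the list with a site on both strands was 1. The standard human sequence is known to carry a placeholder base in the mitochondrial reference that the cells' DNA lacks at this position. Such a base would be missing from all tags, but the plus-strand share was 65.9% (95% Clopper-Pearson interval 49.4 to 79.9), and how the aligner treated these tags was not examined, so this explanation stays open. No biological explanation was tested.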
